A study of Mus musculus with 4 samples.

How the data were processed

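Bone marrow preproB cells of 4 mouse samples, 2 controls and 2 with the Cebpa enhancer deleted, were compared on 1-colour (Cy3) Agilent whole-genome expression arrays. Per the labels' protocols, RNA was taken from sorted cells with Trizol, cleaned on columns, amplified linearly, labelled and hybridised. All 4 arrays lay on 1 slide and were read in 1 scan, so slide and scan cannot differ between the groups.

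Per the file headers, the authors' deposited scanner files came from Agilent Feature Extraction (version 10.7.3.1), and each holds the intensity of 44397 spots per array: the mean and median signal, the local background, and a background-corrected processed signal, with flags per spot. Per the file headers, probe positions refer to mouse build mm9. The authors also deposited 1 table of 31597 named rows on a log2 scale with 1 decimal. Its steps are not given in the sources used here. Each column of that log2 table had a median of 6.5, and over 24810 genes with 1 spot its values correlated at 0.9998 to 0.9999 with the log2 median signal of the matching array, so the scale is log2 with no background subtraction visible. The equal medians show a normalization between arrays whose method stays unknown.

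Control spots were left out, as were spots flagged as non-uniform or as population outliers (126 to 162 per array). Signals were taken as log2 of the processed signal minus each array's 75th percentile, and the spots of a probe were averaged. The 39429 probes were named by accession through the RefSeq table of assembly GRCm38.p6, used for names alone: 26581 matched, 2892 of them with an updated symbol, and the others kept the name in the file. A gene was represented by its brightest probe, and 3995 genes had more than 1 tested probe. A gene was tested if its probe was well above background on both arrays of at least 1 group, which left 24286 probes and 19394 genes. A probe well above background on no array of a group has only a bound there.

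Groups were compared with lmFit and eBayes in limma 3.58.1 under R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Of 26 gene lists fixed before the data were examined, the 24 with at least 5 tested members, without the sex-linked list, were tested with limma's camera at a preset inter-gene correlation of 0.01; camera with an estimated correlation and fry stood beside it. Directional fry tests whether a list's genes move on balance one way, and neither fry test compares a list with other genes. The genes named were fixed by a rule in the design. It took the 12 largest changes in each direction past the threshold with no overlap between groups, filled up from the smallest p among genes at least 2-fold apart, and left out sex-linked genes and names that are accessions, clone names or positions. It added up to 4 tested members of each list by p, a set of C/EBP, lymphoid, myeloid and gate genes, and the sex-linked genes as a check of the labels. Some genes that the rule takes are not reported here.

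The fit was tested on simulated arrays of 19388 genes with the spread estimated from the data. For the comparison of the EnhDel and control groups, it called 0 of 50 genes with a log2 change of 1 and 24 of 50 with 2. It called 38 of 50 with 3 and 46 of 50 with 4. It also called 7 of the other genes. Of those other genes, 20 had been lowered by 1 for a list test, so not all 7 calls need be false. Simulated genes varied independently and with the same spread in both groups. The real EnhDel arrays lay further apart than the control arrays (SD of log2 differences 0.611 against 0.333), so these rates need not hold for them.

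The alternatives were normexp background correction with an offset of 50, quantile normalization, median scaling, no filter on dim probes, a filter at all 4 arrays, the mean of a gene's probes, every probe on its own, the replicate number as a block, each array left out, an intensity trend with robust variance, the authors' deposited values and other list tests. Cyclic loess between arrays was added after seeing the data. In an added version of normexp, 6 spots of EnhDel replicate 1 with a local background above 5 times the array's median took that median, because a local background of up to 10210 had distorted the planned fit of that array; this repair was also chosen after seeing the data, and both versions are given. The arrays' lowest signals well above background were 12.2 to 14.4, which sets how low a level could be measured.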

Results

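RNA was profiled in preproB cells, an early stage of B-cell development, sorted from the bone marrow of C57BL/6 mice as lineage-negative cells with B220 and CD43 but without BP1 and CD24. The mice carried loxP sites around the enhancer that lies 37 kb downstream of Cebpa, the gene of the myeloid transcription factor C/EBPα. Mice of both groups were given 3 doses of pIpC, a synthetic double-stranded RNA that induces interferon, and cells were taken 5 weeks later. The EnhDel group also carried the interferon-inducible Mx1-Cre recombinase, and the control group had the floxed enhancer without Cre. Each group had 2 arrays (n = 2), and each array measured the RNA of 1 sample in 1 colour. Control replicate 1 was labelled as a female of 26 weeks, and the other samples as males of 24 weeks. Between 23491 and 25580 probes per array, 59.6% to 64.9% of the probes, were well above background, and no spot was saturated. The number of arrays limits the precision. The control samples are thus labelled as different animals. The female label of control replicate 1 was not borne out by its sex-linked genes (below), so their independence rests on labels that are in part contradicted. The labels of the EnhDel samples are alike in sex and age, but Xist was well above background on 1 of their arrays alone, so these did not carry the same RNA. P-values measure only the spread between these samples.

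The comparison asked how loss of the Cebpa enhancer altered gene expression in preproB cells. Only the EnhDel group carried Mx1-Cre, so enhancer loss and the presence of Cre cannot be told apart here. Cebpa signal was 1271 and 927 on the control arrays and 125 and 287 on the EnhDel arrays, so both EnhDel values lay below both control values. The normalized log2 difference was -2.41 ± 0.44 (SE, n = 2 per group), or 5.32-fold lower with a 95% interval of 2.33 to 12.2. In limma's fit over all genes the adjusted p (Benjamini-Hochberg) was 0.238. The Cebpa probe lies on chromosome 7 from 35906517 to 35906576 in build mm9. Its exon or UTR was not worked out, since no mm9 annotation was used here. The probe reads the transcript and not the enhancer, so it does not measure the deletion itself.

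Among the other C/EBP genes, Cebpe, which acts late in granulocyte development, had a log2 difference of -3.41 ± 1.29 (SE) and was well above background on 1 of 2 EnhDel arrays. It differed by -1.54 without EnhDel replicate 1, by -1.41 with the repaired normexp background correction and by -0.18 with the unrepaired one (both described below). Without EnhDel replicate 2 it differed by -5.29. That value rests on -7.34 on EnhDel replicate 1, below that array's lowest signal well above background (-6.19), and is not a measured size. Cebpd differed by -0.70 ± 0.25 (-0.44 without EnhDel replicate 2) and Cebpb by 0.57 ± 0.17 (0.36 with median scaling). Cebpg, the neighbour of Cebpa on chromosome 7, differed by -0.04 ± 0.15. None of these 4 passed limma's adjusted threshold in the main fit, with adjusted p from 0.382 to 0.936. The C/EBP family list holds 6 genes, Cebpa itself among them, so it is not independent of the Cebpa result. The list had a median of -0.37. By limma's camera it had an adjusted p of 0.0896 with a preset inter-gene correlation and of 0.536 with an estimated correlation. It passed with the preset correlation when 1 array was left out, at adjusted p = 0.0301 without control replicate 1, 0.0121 without control replicate 2 and 0.0315 without EnhDel replicate 2, but not without EnhDel replicate 1, at 0.243. Its median was -0.04 with the filter at all 4 arrays and -0.05 with the unrepaired normexp. The 10 tested genes around the Cebpa locus had a median of -0.03, a mean of 0.11 and an adjusted p of 0.856 by camera.

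**Figure D1:**
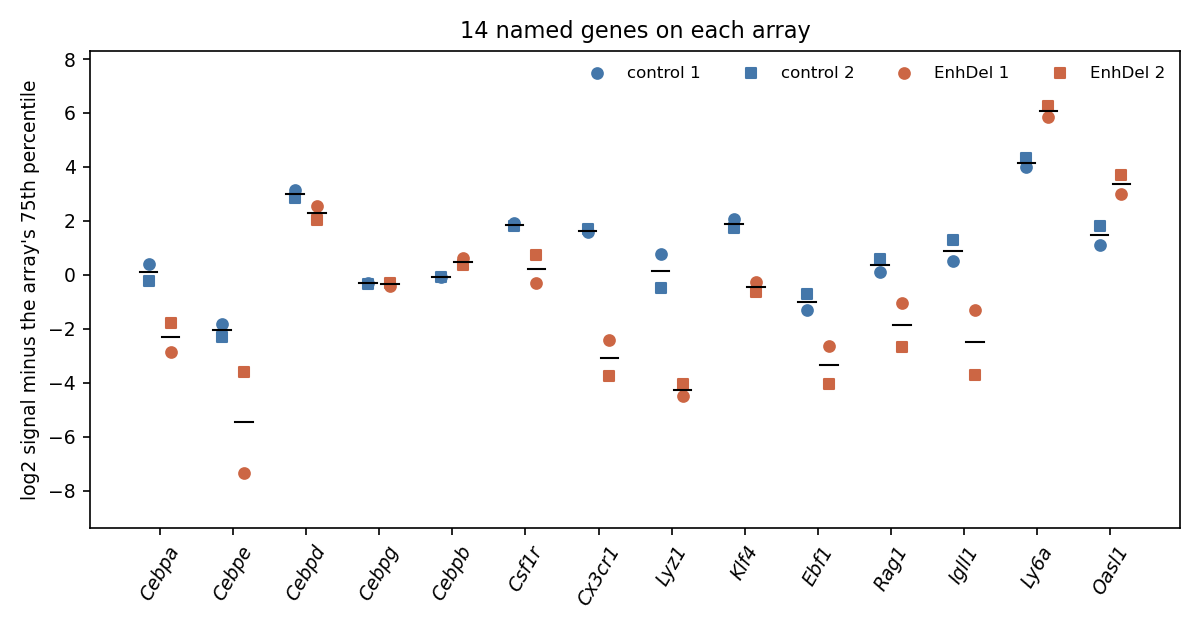
Normalized log2 signal (vertical axis, log2 signal minus the 75th percentile of the array) of 14 genes on each of the 4 arrays. Points are single arrays, coloured by group, and short black lines are group means. Cebpa has a mean of 0.10 on the control arrays and -2.31 on the EnhDel arrays.

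No gene of the 19394 tested passed an adjusted p of 0.05 in limma, where 2171 had an unadjusted p under 0.05 against 970 by chance. The lowest adjusted p was 0.0505. With at least a 2-fold difference and an unadjusted p under 0.05, 470 genes were higher and 371 lower on the EnhDel arrays. The groups did not overlap in 8547 genes, 44.1% of those tested, where chance gives 33.3%. The split of the 2-fold genes varied with the processing: 250 were higher and 418 lower after quantile normalization, 318 and 673 with median scaling, 361 and 143 after normexp background correction, 115 and 254 after normexp with 6 distorting spots repaired, 280 and 439 after cyclic loess, 65 and 123 with the authors' deposited values, 230 and 278 with the filter at all 4 arrays, and 1056 and 465 with no filter. The median of all genes moved from 0.07 to -0.14 with median scaling and to 0.19 with the unrepaired normexp, whose fit of EnhDel replicate 1 was distorted by those spots.

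The count past the threshold rested on which arrays were in the fit. It was 2938 without EnhDel replicate 1, 47 without EnhDel replicate 2, 6 without control replicate 2 and 1 without control replicate 1, in fits that assume the lone array to vary like the other group. Median scaling gave 23 genes and the mean over a gene's probes gave 2. The size of a gene's difference depended on the background handling more than on most other choices. Of the 119 genes named by the rule, besides Cebpa, whose main difference exceeded its SE, 59 became over 1.5 times smaller or changed sign with the authors' deposited values, 53 with the repaired and 44 with the unrepaired normexp, 25 without EnhDel replicate 2 and at most 12 in any other alternative. Bounds given below as at least some fold hold for the main processing alone.

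Among genes at least 2-fold apart that have an ordinary symbol, the 12 lower ones with the smallest p had adjusted p from 0.0708 to 0.111 in limma, none past the threshold. Names that are accessions or clone names were left out beforehand, among them the 1 lower and 1 higher transcript with the lowest adjusted p of all, 0.0505. Fn1, the gene of the matrix protein fibronectin, was not well above background on the EnhDel arrays and was at least 32.3-fold lower, where bounds set the bright group's mean against the lowest signal well above background. Fut7, a fucosyltransferase that makes selectin ligands, differed by -3.48 ± 0.20 (SE). Anxa1, the gene of the phospholipid-binding protein annexin A1, differed by -2.54 ± 0.19, Gcnt2 by -2.96 ± 0.19, Rin2 by -2.80 ± 0.16 and Fkbp1b by -2.01 ± 0.15. Nav1 differed by -3.14 ± 0.17 and was well above background on 1 of 2 EnhDel arrays. Ankrd55 was at least 3.08-fold, Serpinb10 at least 2.25-fold, Apbb1 at least 1.68-fold and Ppp1r26 at least 1.59-fold lower. With the unrepaired normexp the differences of Ankrd55, Serpinb10, Apbb1 and Ppp1r26 turned positive, and with the repaired one they did not, but shrank to between -0.52 and -0.31. With the repaired normexp Fn1 differed by only -2.996, under its bound, Rin2 by -1.57, Nav1 by -1.29 and Gcnt2 by -1.17, and with the unrepaired one Fn1 by -1.73, Rin2 by -0.51, Fkbp1b by -0.51, Nav1 by -0.10 and Gcnt2 by -0.03.

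The 12 higher genes chosen in that way had adjusted p from 0.0708 to 0.155 in limma, also none past the threshold. Spint1, a membrane-bound protease inhibitor, differed by 2.86 ± 0.16 (SE) and was well above background on 1 of 2 control arrays. Ehd3, an endocytic recycling protein, differed by 2.16 ± 0.14, Stac2 by 2.30 ± 0.22, Duxbl2 by 1.87 ± 0.16, Ppic by 1.84 ± 0.17 and Scn3a by 1.52 ± 0.15, and Trim30c was 2.83-fold higher. Fam71b differed by 2.00 ± 0.17 and Nrip2 by 1.71 ± 0.15. Dapl1 was at least 4.45-fold, Disp2 at least 2.01-fold and Bmp4, a secreted growth factor, at least 1.77-fold higher. With the repaired normexp Spint1 differed by 1.19, Fam71b by 1.03, Nrip2 by 1.04, Trim30c by 0.94, Dapl1 by 0.73, Bmp4 by 0.39 and Disp2 by 0.35, the last 3 under their bounds.

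Of the 24 gene lists tested, 9 fell and 4 rose on the EnhDel arrays by camera with the preset correlation. Some lists share members, so their calls are not separate results. Igll1, Rag1 and Rag2 are in the lymphoid priming list and in B-lineage lists. Klf4 and Csf1r are in both the monocyte and the myeloid progenitor lists. No list was called with an estimated correlation, where 1 list had an unadjusted p under 0.05 and the lowest adjusted p was 0.536. No list was called by fry's directional test, with 5 lists at an unadjusted p under 0.05 and a lowest adjusted p of 0.104. By fry's test for change in either direction 10 lists were called. These were 7 of the 13 camera calls and the Notch (adjusted p = 0.00506), Myc (0.0119) and eosinophil, basophil and mast cell (0.0416) lists, and they left out the S phase (0.121), mitosis (0.137), interferon-stimulated (0.121), lymphoid priming (0.0781), early B-lineage (0.137) and pre-B receptor (0.119) lists. With the unrepaired normexp, camera with the preset correlation lost the hematopoietic stem and progenitor, neutrophil granule and T cell calls (adjusted p = 0.217, 0.167 and 0.0806, at medians of -0.22, -0.03 and 0.68) and called plasmacytoid dendritic cell genes lower (0.0255), Myc and ribosome biogenesis genes lower (0.0161) and eosinophil, basophil and mast cell genes higher (0.00101). No member of any list passed limma's threshold over all genes, so the members named here are given as values.

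Genes of monocytes and macrophages fell as a list (23 genes, adjusted p = 2.18e-05 by camera; adjusted p = 0.536 with an estimated correlation). The mean log2 difference was -1.15 and the median -0.10 (from -0.33 to 0.001 over all alternatives), and 8 members were lower adjusted over the list alone. The fractalkine receptor gene Cx3cr1 differed by -4.72 ± 0.47 (SE), the lysozyme gene Lyz1 by -4.40 ± 0.47 (-2.26 with the unrepaired normexp), Ms4a6c by -2.32 ± 0.20 and the transcription factor gene Klf4 by -2.35 ± 0.23. The receptor gene for M-CSF, Csf1r, differed by -1.63 ± 0.39, or -0.51 with the mean of its probes and -0.45 with the authors' deposited values. Myeloid progenitor regulators also fell (18 genes, adjusted p = 0.000436 by camera; 0.536 as the adjusted p with an estimated correlation), with a median of -0.28 and 5 members lower adjusted over the list alone. That median was -0.34 on EnhDel replicate 1 and -0.10 on EnhDel replicate 2, and over all alternatives it ranged from -0.48 with median scaling to -0.10 without EnhDel replicate 1. In that list Hp, the haptoglobin gene, differed by -2.68 ± 0.59 (-0.74 with the unrepaired normexp) and Runx1 by -0.85 ± 0.15. Spi1, the gene of the myeloid and B-cell regulator PU.1, differed by -0.24 ± 0.30 (from -0.615 to 0.648 over all alternatives).

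Neutrophil granule genes fell (17 genes, adjusted p = 0.00102 by camera; adjusted p = 0.573 with an estimated correlation), with a median of -1.51 on EnhDel replicate 1 and -0.33 on EnhDel replicate 2. Adjusted over the list alone, 2 members were lower and 1 was higher. Anxa1, at -2.54, was among its members. Pglyrp1 differed by 0.81 ± 0.17 (SE), Lcn2 by 0.83 ± 0.21 (0.25 and 0.30 with the authors' deposited values) and Csf3r, the G-CSF receptor gene, by 0.02 ± 0.22. Without EnhDel replicate 1 this call was lost, at an adjusted p of 0.243 by camera. The median of -1.04 over both arrays was -0.51 with the repaired normexp, -0.30 with no filter on dim probes and -0.03 with the unrepaired normexp.

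Early B-lineage regulators fell (19 genes, adjusted p = 0.00341 by camera; 0.536 as the adjusted p with an estimated correlation), and so did genes of the pre-B receptor and B-lineage surface (24 genes, adjusted p = 0.0131 by camera; adjusted p = 0.573 with an estimated correlation). Their medians were -0.18 and -0.08 (over all alternatives from -0.38 to -0.08 and from -0.29 to 0), their means -0.55 and -0.63, and no member of either list passed adjusted over the list alone. Ebf1, which specifies the B lineage, differed by -2.34 ± 0.53 (SE; -1.15 with the unrepaired normexp), Lef1 by -2.31 ± 0.65, and the recombinase genes Rag1 and Rag2 by -2.20 ± 0.59 and -2.75 ± 1.01, with Rag2 well above background on 1 of 2 EnhDel arrays. Without EnhDel replicate 2, Lef1 differed by -1.42, Rag1 by -1.38 and Rag2 by -1.28. Igll1, a surrogate light chain gene of the pre-B receptor, differed by -3.40 ± 0.86 (-2.21 without EnhDel replicate 2) and Cd79a by -0.79 ± 0.20. Tcf3 differed by -0.18 ± 0.15 and Ikzf1 by -0.26 ± 0.32 (from -0.67 to 0.16 over all alternatives). Il7r differed by 0.16 ± 0.16 (negative with median scaling and with the unrepaired normexp). Dntt differed by 0.13 ± 0.24 (from -0.18 to 0.40 over all alternatives). Pax5 was not well above background on both arrays of either group. The early B-lineage call was lost with the authors' deposited values (adjusted p = 0.0628 by camera, at a median of -0.15) and cyclic loess (0.0549, at -0.16). The pre-B receptor call was lost after quantile normalization (0.177, at a median of -0.03), with the authors' deposited values (0.505, at 0) and cyclic loess (0.252, at -0.04).

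Lymphoid priming genes fell as a list (16 genes, adjusted p = 0.000287 by camera; adjusted p = 0.536 with an estimated correlation), with a median of -0.15 (from -0.39 to -0.09 over all alternatives), a mean of -0.88 and 6 members lower adjusted over the list alone. Cnn3 differed by -2.93 ± 0.42 (SE), Cd34 by -1.47 ± 0.37 (-0.80 with the authors' deposited values), Cd27 by -0.99 ± 0.24 (positive with the unrepaired normexp) and the cytokine receptor gene Flt3 by -0.61 ± 0.16 (-0.28 with the mean of its probes). Hematopoietic stem and progenitor genes also fell (19 genes, adjusted p = 0.0146 by camera; 0.536 as the adjusted p with an estimated correlation), with a median of -0.44 (from -0.64 to -0.09 over all alternatives) and members on both sides. Erg differed by -2.59 ± 0.36 (-1.14 with the repaired and -0.09 with the unrepaired normexp) and Kit by -0.77 ± 0.15 (-0.25 with the unrepaired one), while Ly6a, which encodes the stem cell antigen Sca-1, differed by 1.90 ± 0.23 and Tal1 by 1.45 ± 0.25 (0.75 with the repaired normexp). That call was lost with median scaling (adjusted p = 0.173 by camera), at a larger median of -0.64, and without EnhDel replicate 1 (0.18), at a median of -0.43. It was also lost with no filter on dim probes (0.137, at -0.09) and without EnhDel replicate 2 (0.0601, at -0.28).

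Genes of S phase and of mitosis fell together (30 and 28 genes, each with an adjusted p of 2.54e-15 by camera and of 0.536 with an estimated correlation). The S phase median was -0.98, with 28 of 30 members lower, and the mitosis median was -1.51, with 28 of 28 lower. Adjusted over the list alone, 1 member of each list was lower. The replication genes Gins1 and Chaf1a differed by -1.58 ± 0.43 (SE) and -1.25 ± 0.28, and the mitotic genes Tpx2, Bub1b and Aurkb by -1.44 ± 0.52, -1.30 ± 0.37 and -1.16 ± 0.16. Without EnhDel replicate 2, Gins1 differed by -1.04, Tpx2 by -0.73 and Bub1b by -0.84. Aurkb turned positive with the unrepaired normexp and differed by -0.30 with the repaired one. The shift was unequal between the EnhDel arrays: the S phase median was -0.53 on EnhDel replicate 1 and -1.31 on EnhDel replicate 2, and the mitosis median was -0.68 and -2.37.

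Interferon-stimulated genes rose as a list (34 genes, adjusted p = 1.32e-09 by camera; adjusted p = 0.536 with an estimated correlation), with a median of 0.83 and 33 of 34 members higher. The median was 0.47 on EnhDel replicate 1 and 1.09 on EnhDel replicate 2, and no member passed adjusted over the list alone. Oas1a and Oasl1, of the antiviral 2',5'-oligoadenylate synthetase family, differed by 2.21 ± 0.54 (SE) and 1.89 ± 0.36, and Lgals3bp by 0.90 ± 0.17.

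Erythroid and megakaryocyte genes rose as a list (20 genes, adjusted p = 2.3e-08 by camera; adjusted p = 0.536 with an estimated correlation), with 19 of 20 members higher. Their median was 1.57, or 1.31 with the 4 members not well above background in the control group at their bound, and 11 members were higher adjusted over the list alone. The median was 0.60 with the authors' deposited values and 0.64 with the repaired normexp, where that of the interferon-stimulated list was higher, at 0.625 and 0.73. The carbonic anhydrase gene Car1 differed by 1.18 ± 0.15 (SE), Gp9 was at least 2.70-fold higher and Klf1, an erythroid transcription factor gene, at least 2.07-fold higher, but they differed by only 0.43 and 0.56 with the repaired normexp, under these bounds. Dim genes in general were shifted upward: those with a mean normalized log2 signal between -6 and -4 had a median difference of 0.34. The 363 below -6, Klf1 among them, had 0.89. The filter can enlarge that value, since genes were tested only if well above background on both arrays of at least 1 group. The arrays' lowest normalized log2 signals well above background were -6.325 to -6.05.

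T cell genes rose (22 genes, median 0.58, adjusted p = 0.00138 by camera; adjusted p = 0.563 with an estimated correlation), as did genes of NK and innate lymphoid cells (22 genes, median 0.71, adjusted p = 0.00181 by camera; adjusted p = 0.536 with an estimated correlation). With the authors' deposited values the medians were 0.30 and 0.35, with median scaling the T cell median was 0.38, and without control replicate 2 the NK median was 0.365. Adjusted over the list alone, 3 T cell genes were higher, and 7 NK genes were higher and 1 lower. The T cell regulator genes Gata3 and Tcf7 differed by 2.26 ± 0.44 (SE) and 2.18 ± 0.53, and Cd3g by 1.06 ± 0.14. Gzmb, the granzyme B gene, was at least 9.76-fold higher, the chemokine gene Xcl1 differed by 2.31 ± 0.25 and Eomes by 1.30 ± 0.17, and Klrk1, which turned positive with the unrepaired normexp, differed by -1.24 ± 0.17. With the repaired normexp Gata3 differed by 0.98, Tcf7 by 1.27, Cd3g by 0.55, Xcl1 by 1.42, Eomes by 0.69 and Gzmb by 1.65, under its bound. Both calls were lost without EnhDel replicate 1, each at an adjusted p of 0.373 by camera, at medians of 0.575 for T cells and 0.50 for NK cells.

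**Figure D2:**
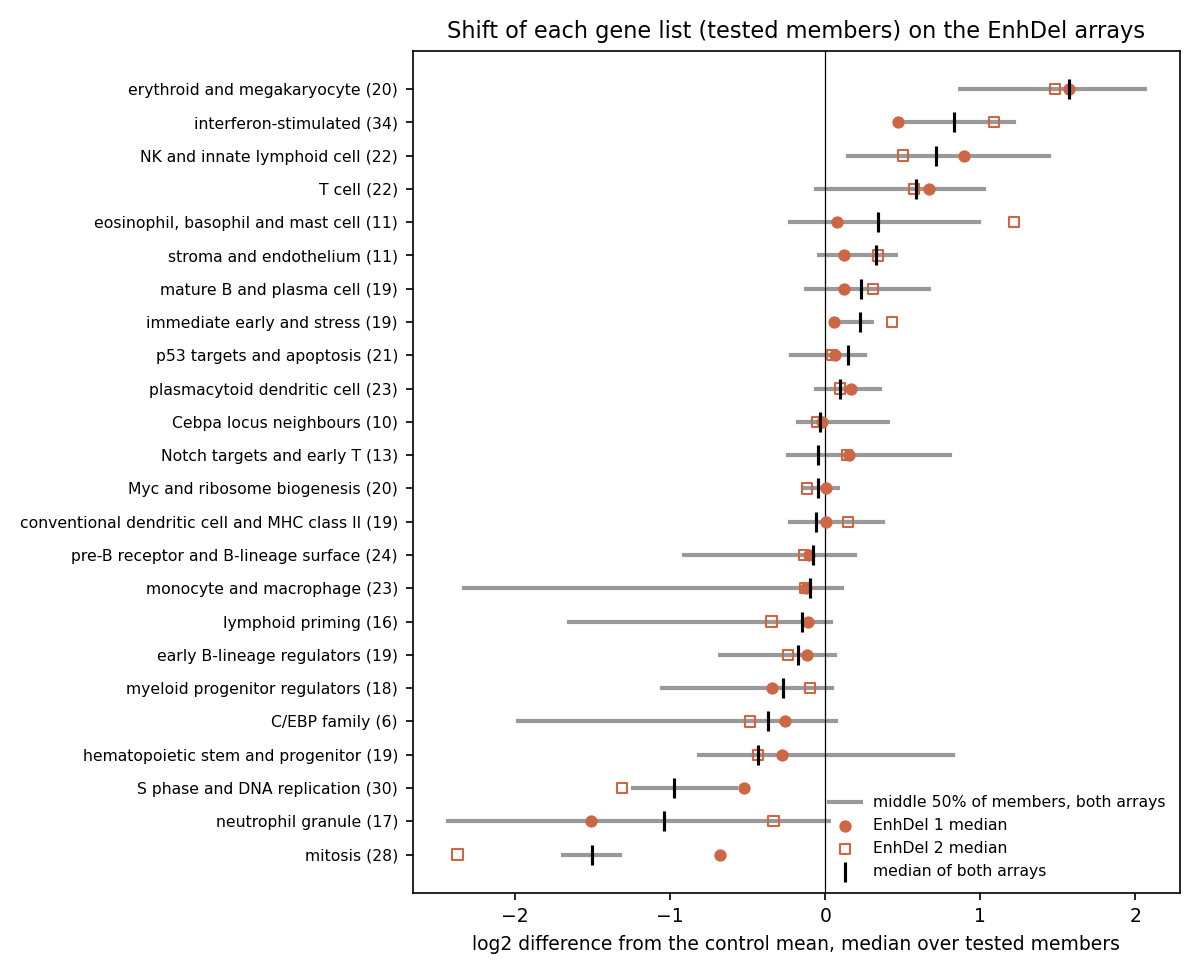
Median log2 difference from the control mean (horizontal axis) of each gene list, with the number of tested members in brackets, on EnhDel replicate 1 (filled circles), on EnhDel replicate 2 (open squares) and over both (black ticks); grey bars span the interquartile range of the members. Mitosis lies lowest, at -1.51 over both arrays, and the erythroid and megakaryocyte list highest, at 1.57 in the main setting.

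The remaining lists were not called by camera. Plasmacytoid dendritic cell genes had a median of 0.09 (23 genes, adjusted p = 0.374), but were called higher after quantile normalization (adjusted p = 0.0317), with the authors' deposited values (0.011) and after cyclic loess (0.0131). In that list Ccr9 differed by 0.42 ± 0.19 (SE) and Tlr7 by 0.52 ± 0.19 (0.11 and 0.26 with the unrepaired normexp), Cd8b1 by 0.88 ± 0.25 and Irf7 by 1.20 ± 0.55 (0.44 without EnhDel replicate 2 and 1.96 without EnhDel replicate 1). Eosinophil, basophil and mast cell genes had a median of 0.34 (adjusted p = 0.374) and were called higher with the filter at all 4 arrays (0.00937) and without EnhDel replicate 1 (0.027); Il1rl1 differed by 1.91 ± 0.26 (0.86 with the repaired normexp and 0.50 with the authors' deposited values). Medians were 0.23 for mature B and plasma cells (adjusted p = 0.367), -0.06 for conventional dendritic cells and MHC class II (0.789; mean 0.04), 0.33 for stroma and endothelium (0.426) and 0.14 for p53 targets and apoptosis (0.482), the last with a mean of -0.10 and a lower direction in the test. They were 0.22 for immediate early and stress genes (0.367), -0.05 for Myc and ribosome biogenesis (0.124; mean 0.001) and -0.05 for Notch targets and early T cell genes (0.982), where the mean was 0.19 and members moved both ways, 3 higher and 2 lower adjusted over the list alone. Each median in this paragraph moved by over 1.5 times under at least 1 alternative, and those of the plasmacytoid and conventional dendritic cell, p53, Myc and Notch lists changed sign. Among the 3 gate antigens tested, Spn, which encodes CD43, differed by -0.12 ± 0.14, Ptprc by 0.49 ± 0.33 and Cd24a by -0.82 ± 0.47. Ptprc and Cd24a stood at 0.06 and -0.17 on EnhDel replicate 1, and at 0.92 and -1.48 on EnhDel replicate 2. B220 is a product of Ptprc, but whether the Ptprc probe reads B220 alone was not worked out. Enpep, which encodes BP1, was not well above background on any array. Cd24a was well above background on all 4 arrays, although the sort took cells without CD24. Its signals were 4779 and 6366 on the control arrays and 4386 and 1910 on the EnhDel arrays. The arrays read RNA and not the surface protein, so the purity of the sort was not measured.

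The sex-linked genes did not follow the labels. Control replicate 1 is labelled female, yet neither of its 2 Xist probes was well above background and its Y-linked genes Eif2s3y and Ddx3y had signals of 4917 and 3116, against 6840 and 3474 on control replicate 2, labelled male. EnhDel replicate 2 is labelled male, yet the 2 Xist probes had signals of 1551 and 597 there. On that array Eif2s3y and Ddx3y stood at 2635 and 1560, against 5561 and 3624 on EnhDel replicate 1. EnhDel replicate 2 also stood apart across all genes. The SD of its log2 difference from EnhDel replicate 1 was 0.61, against 0.33 between the control arrays. EnhDel replicate 1 lay closer to control replicates 1 and 2, at SDs of 0.515 and 0.532, than to EnhDel replicate 2. For tested genes with a mean normalized log2 signal below -6, the filter limits the reading, as said above. Their median difference from the controls was 0.93 on EnhDel replicate 2 and 0.82 on EnhDel replicate 1. Genes between -6 and -4 had 0.51 on EnhDel replicate 2 and 0.16 on EnhDel replicate 1, and those above 4 had -0.16 and 0.05.

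**Figure D3:**
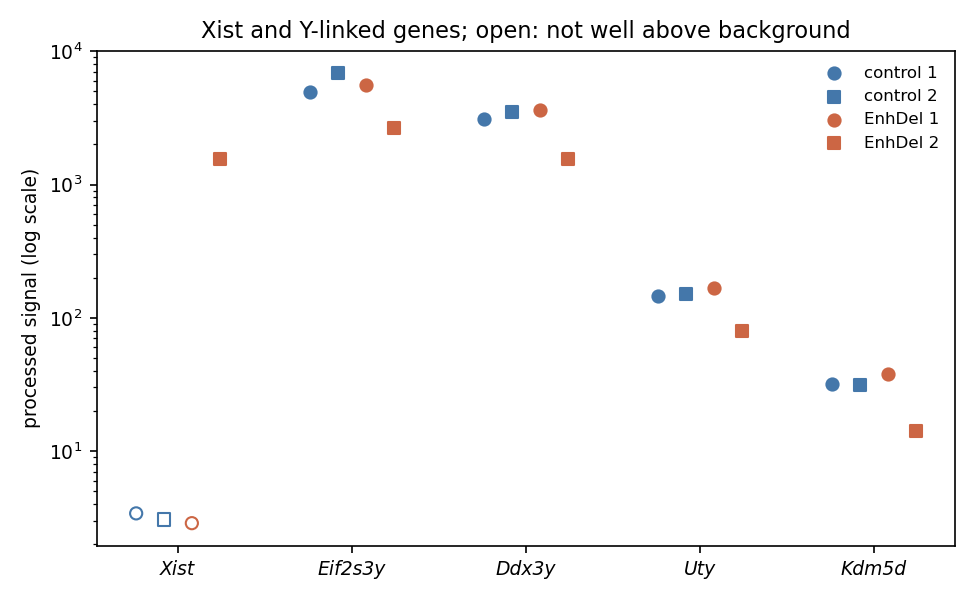
Processed signal (vertical axis, log scale) of the brightest probe of Xist and of 4 Y-linked genes on each array; open symbols are not well above background. Xist is above background on EnhDel replicate 2 alone, where the Y-linked genes are lower than on the other 3 arrays.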

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

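All tests in this part except that of cyclic loess on the S phase and mitosis genes were chosen after the results were seen, and cyclic loess was itself added after seeing the data. One signal lay outside the main comparison: Xist was not tested, since no group had it well above background on both arrays. On EnhDel replicate 2 it stood 6.84 above the control floor on the log2 scale, at least 114-fold.

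That array also held less signal of each of 4 Y-linked genes than the other 3 arrays, with a median log2 difference of -1.13 and a range from -1.27 to -0.96, or a median share of 0.459. RNA of 1 female animal alone is argued against by 4 Y-linked genes well above background there, and RNA of 1 male animal alone by 2 Xist probes well above background. An exchange of control replicate 1 with EnhDel replicate 2 is argued against by Cebpa, which lay 1.56 lower on EnhDel replicate 2 than on control replicate 2 (log2 difference -1.56). RNA of both sexes on 1 array, by a pool of animals or by mixing, may account for the pattern, as the like drop of the Y-linked genes (-1.13) is what it needs. On control replicate 1, RNA of a female animal alone, as its label says, is argued against by 4 Y-linked genes well above background there and by neither Xist probe being so. How that label came about, and at which step RNA would have been joined on EnhDel replicate 2, stays open.

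The 58 genes of S phase and mitosis had a median log2 difference of -1.29. An array-wide trend with signal strength as the whole cause is argued against by the median of -1.35 that remained after cyclic loess. EnhDel replicate 2 was weighed as the sole source. On EnhDel replicate 1 the median was -0.62. In 10000 random lists matched on mean signal, the middle 95% of medians ran from -0.01 to 0.11. Both EnhDel arrays lay below both control arrays in 26 of 30 S phase and 27 of 28 mitosis genes. The mitosis median was -1.80 without control replicate 1 and -1.25 without control replicate 2, so the controls also differed. Genes of such lists can move together, as those of random lists need not, so whether EnhDel replicate 2 was the sole source stays open. A biological difference from the loss of the enhancer may be involved, and a different make-up of the sorted cells stays open, both untested here.

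The 64 genes of the erythroid, T cell and NK lists had a median log2 difference of 0.85, while dim genes in general were shifted upward on the EnhDel arrays. In matched random lists, drawn with the main processing alone, the middle 95% of medians ran from 0.04 to 0.26 against 0.85. Genes of the 3 lists can move together, as those of random lists need not, so that range alone cannot decide. A trend with signal strength as the whole cause is argued against by the median of 0.71 that remained after cyclic loess. EnhDel replicate 2 as the sole source is argued against by the median of 1.07 on EnhDel replicate 1, above the 0.72 on EnhDel replicate 2. Matched lists on EnhDel replicate 1, with the same limit, ran from -0.01 to 0.15. A lower share of the sorted cell type, with all other cell types higher alike, was set against the monocyte and macrophage list. Its median was -0.10, with an upper quartile of 0.11 below the lower quartile of 0.36 of the 3 lists. That list cannot decide it, because a fall of the myeloid regulator gene Cebpa could itself lower monocyte genes. Some members, such as Irf8, were also bright in both groups (means of 8.16 and 8.10). A lower share of the sorted cells therefore stays open. RNA of other cells that passed the sort, or expression of these genes in the sorted cells themselves, may account for the shift of 0.85, and neither was tested; the lineage-negative gate would remove most mature cells of these types.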

How the results depend on the processing

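Cyclic loess, and normexp with a repaired local background, were chosen after seeing the data. The Cebpa difference stayed negative under all 16 alternatives, from -2.95 (without EnhDel replicate 2, and -1.87 without EnhDel replicate 1) to -1.42 (unrepaired normexp, and -2.04 when repaired). In limma its adjusted p ranged from 0.124 with median scaling to 0.513 with the unrepaired normexp, over the alternatives that kept all 4 arrays. It passed the threshold only without EnhDel replicate 1. There the Cebpa difference was smaller than without EnhDel replicate 2, at the same SE of 0.305. That pass therefore reflects the other genes in the adjustment and not stronger evidence on Cebpa. The count of genes past the threshold was 0 in 10 alternatives, 23 with median scaling and 2 with the mean of a gene's probes, and ranged from 1 to 2938 with 1 array left out; the cause was not tested. The count of 2-fold genes at an unadjusted p under 0.05, 841 in the main setting, was 504 with the unrepaired and 369 with the repaired normexp (the cause was not tested), 188 with the authors' deposited values, 508 with the filter at all 4 arrays, where fewer genes were tested, and 1521 with no filter, where more were. It ranged from 779 to 2158 with 1 array left out. The 13 list calls ranged from 10 to 14 except with camera's estimated correlation and with fry, which gave 0 each. Of 126 named genes besides Cebpa, 109 reversed under no alternative, where a reversal counts only if the main difference exceeded its SE. With the unrepaired normexp, in which 6 spots of EnhDel replicate 1 with a local background above the spot distorted the fit, these turned: Ankrd55 (0.705), Apbb1 (1.01), Aurkb (0.846), Batf3 (0.513), Ccne2 (1.16), Cd27 (0.565), Cecr2 (0.788), Hdc (0.591), Ier2 (0.582), Il7r (-0.149), Kif2c (0.063), Klrk1 (0.546), Myc (0.009), Ppp1r26 (0.9), Serpinb10 (0.874), Spp1 (0.66) and the plasmacytoid dendritic cell list (-0.195). None of these turned after the repair. Il7r also reversed with median scaling (-0.043) and Nop58 without EnhDel replicate 2 (0.016, against -0.576 without EnhDel replicate 1); the cause was not tested. With the replicate number as a block, 0 genes passed the threshold and 861 were 2-fold apart at an unadjusted p under 0.05. In that fit 13 lists were called, and Cebpa differed by -2.41. Deviations of same-numbered arrays from their group means correlated at -0.0236 across genes. That value gives no sign of a shared day or batch across genes at large, but cannot exclude one that moved fewer genes. Slide and scan as a block were not run, because all arrays share 1 slide and 1 scan. Signal over background limits dim genes: 18213 of the 19394 tested genes were well above background on all 4 arrays.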

Other observations

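The genes in this paragraph were chosen after their values were seen. Some neutrophil primary granule genes were far apart between the EnhDel arrays while the control arrays lay close together. Normalized log2 signals of Mpo, the myeloperoxidase gene, were 3.83 and 4.08 on the control arrays, -0.76 on EnhDel replicate 1 and 2.88 on EnhDel replicate 2. Those of Ctsg, the cathepsin G gene, were 2.05, 2.44, -4.84 and 1.25 in the same order. Elane, the neutrophil elastase gene, was less far apart, at 0.18, 0.15, -1.35 and -0.43. The surrogate light chain genes went the other way between the EnhDel arrays. Vpreb1 stood at 3.90 and 4.46 on the control arrays, 2.38 on EnhDel replicate 1 and -0.14 on EnhDel replicate 2. Cebpa was lower on EnhDel replicate 1 (-2.85) than on EnhDel replicate 2 (-1.77). F13a1, a coagulation factor gene expressed by monocytes, was at 0.12 and 0.01 on the control arrays. It was at -4.65 on EnhDel replicate 1 and at -7.63, not well above background, on EnhDel replicate 2. With 2 arrays per group these differences between replicates were not tested.

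Siglech and Bst2, typical of plasmacytoid dendritic cells, were measured well above background on all 4 arrays in both groups. Siglech differed by 0.05 between EnhDel and control on the log2 scale, with an adjusted p of 0.917 in limma. Bst2 had normalized log2 signals from 7.33 on EnhDel replicate 2 to 7.55 on control replicate 1. Irf8, which dendritic cells and monocytes express, had 8.23 and 8.08 on the control arrays and 8.17 and 8.03 on the EnhDel arrays. Of the markers used in the sort, B220 is also carried by these cells.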
